A study of Homo sapiens with 13 samples.

How the data were processed

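The series holds 13 arrays from U87MG, an established human glioblastoma cell line that the labels describe as glial. For expression, 4 cultures received scrambled siRNA and 5 received siRNA against AEBP1, each at 100 nM, and RNA was taken 46 h after transfection. The labels call these biological replicates. For chromatin immunoprecipitation on arrays (ChIP-chip), chromatin was fixed with 1% formaldehyde, sheared to about 500 bp and precipitated with an AEBP1 antibody, and DNA was amplified by ligation-mediated PCR. There were 2 immunoprecipitations, each hybridised to 2 array designs that cover different promoters. No label says that the immunoprecipitations came from separate cultures, so their spread may be technical.

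The expression values are deposited log2 values per probe set, made with RMA per the submitters' processing notes; the RMA version and the settings are not given in the sources used here. The table holds 54675 probe sets, of which 62 are Affymetrix control probe sets. Values below 0 occur on every array, at 1140 to 1568 probe sets per array, and the quartiles differ between arrays, so the deposited values do not lie on a common distribution. Lower-signal probe sets were left out unless at least 4 of the 9 arrays reached log2 5, which kept 26164.

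Scanner files of the ChIP arrays hold intensity values made with Agilent Feature Extraction 10.5.1.1, per the file headers: the headers record background subtraction with spatial and multiplicative detrending, and a dye normalization whose method they give as a code only. Coordinates are those of the files, in build hg18. Cy5 carried the immunoprecipitated DNA and Cy3 the input DNA on all 4 arrays, per the labels, and dyes were not swapped. The authors' series matrix of the ChIP arrays holds deposited log10 ratios of Cy5 over Cy3; they differed from the scanner files' log10 ratio by at most 0.005, so scale and direction are known. Their column medians were 0 on 3 arrays and -0.00666 on immunoprecipitation 2 of design 2. Where these values served as an alternative, they were centred on each array's median over the spots not flagged as outliers. All 4 ChIP arrays were scanned on 1 day, and each array was a slide of its own, so no scan batch could be tested.

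Expression was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, AEBP1 siRNA minus scrambled siRNA, with Benjamini-Hochberg adjustment and a threshold of 0.05. No table used here pairs the expression probe sets with genes. The test was therefore run per probe set and not per gene, at most 2 probe set identifiers are printed per direction, and the AEBP1 transcript, the gene lists in expression and the comparison of bound with changed genes were not analysed here. The knockdown itself is for that reason not checked here. The 4 printed probe sets were chosen after their values were seen, as those with the lowest p in each direction whose groups did not overlap.

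For ChIP, log2 of the processed Cy5 over the processed Cy3 signal was centred on each array's median, without loess or quantile normalization. Control spots and outlier-flagged spots were left out, as were the 12 and 7 probes without a position. Window means were taken over probes within 500 bp of each probe, with at least 3 probes, and turned into z-scores from their median and the spread of the window means below it. A window was called where both arrays reached a threshold z, the smallest step of 0.1 from 2 upwards at which windows equally low on both arrays numbered at most 5% of those called. Called probes within 1000 bp were merged into regions. The named regions are the 10 with the highest lower z-score among those whose probes name a gene, a rule set with the tests and their main settings before the data were examined; the AEBP1 promoter belongs to the same rule. Gene names are those of the array design, and 16500 of its 17650 genes with a window carry or could be matched to a current symbol in the reference tables (GRCh38.p14, used for names only). No annotation of the files' build was used, so whether a region is exonic, intronic or upstream is not given.

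27 gene lists fixed before the data were examined were compared with the genes that have a region by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. Correlations between immunoprecipitations run across probes or windows, which are not independent replicates. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. Alternatives covered the filter, normalization, variance model, replicate numbers and left-out arrays for expression, and the background correction, values, dim probes, window, error rate, combination of arrays and GC content for ChIP.

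The limma step was tested on simulated data drawn from the real means and spreads of the 26164 probe sets. The noise was independent between arrays and probe sets. Without a block the step recovered 15 of 100 probe sets changed by 1 on the log2 scale and 76 of 100 changed by 2, with 9 false calls. With a block for the spike-in sets described with the results it recovered 39 and 91 of 100, with 11 false calls. Only the test with the block included the real shifts of these sets. The numbers without a block therefore describe arrays without sets and may not hold for the real ones. The region step was tested on the real arrays with immunoprecipitation 2 shifted along the genome, which removes shared signal, and with peaks of known height added to both. On design 1, 41 of 100 peaks of log2 height 2 and 95 of 100 of height 4 were recovered, and 58 regions held no added peak. On design 2 these numbers were 56, 100 and 122. With no peaks added, 2 and 3 regions were called. With peaks added, the threshold z dropped from 3.2 and 3.6 to 2.3 on both designs, and the mirrored lower tail understated the false regions. The number of arrays limits the precision of every value.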

Results

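Silencing of AEBP1, a transcriptional regulator also called adipocyte enhancer-binding protein 1, was profiled in U87MG cells on 9 expression arrays, 4 with scrambled siRNA and 5 with AEBP1 siRNA. Binding of AEBP1 to promoters was measured in the same line by ChIP-chip on 4 arrays, with 2 immunoprecipitations on each of 2 array designs. Of the ChIP probes, 79.4% to 86.1% per array were well above background in both channels.

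The first comparison asks which transcripts differ after AEBP1 silencing. No probe set passed the threshold: limma called 0 of 26164 probe sets at adjusted p below 0.05, and 1135 had an unadjusted p below 0.05, of which 673 were lower and 462 higher with AEBP1 siRNA. This split turned to 718 lower and 1420 higher when AEBP1 siRNA replicate 2 was left out. For independent arrays without a group difference, a share of 0.05 of the probe sets is expected at an unadjusted p below 0.05. The 1135 of 26164 are a smaller share, so this count shows no response by itself. It cannot show that there was none, since the arrays fell into sets, described next, that this fit leaves in its error. The strongest difference was at probe set 201484_at, with a log2 signal of 9.16 ± 0.22 (SD, n = 4) in scrambled siRNA and 7.34 ± 0.37 (SD, n = 5) in AEBP1 siRNA, a difference of -1.82 ± 0.24 (SE; limma adjusted p = 0.287). Probe set 202441_at was at 9.61 ± 0.23 (SD, n = 4) and 7.95 ± 0.40 (SD, n = 5; limma adjusted p = 0.294). In the other direction, 236126_at was at 5.52 ± 0.36 (SD, n = 4) and 6.98 ± 0.45 (SD, n = 5), with a limma adjusted p of 0.382, and 226793_at at 7.13 ± 0.55 (SD, n = 4) and 8.43 ± 0.21 (SD, n = 5), with a limma adjusted p of 0.449. At these 4 probe sets the groups did not overlap. AEBP1 itself was not analysed here on the expression arrays, because no table used here names the probe sets.

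The 9 arrays fell into 4 sets by the signal of the poly-A spike-in controls, which are bacterial transcripts added to the RNA before labelling. The mean spike-in log2 signal was 3.30 in the set of replicates 2 of both groups, 5.04 in that of scrambled replicate 4 and AEBP1 siRNA replicate 5, 6.86 in that of scrambled replicate 3 and AEBP1 siRNA replicates 3 and 4, and 9.83 in that of replicates 1. Each set thus held both groups. With the set as a block, chosen after the data were seen, limma called 42 probe sets at adjusted p below 0.05. Of these 42, 31 fell by 1.06 to 1.93 and 11 rose by 1.09 to 1.76 on the log2 scale, and all 42 had the same direction without the block. At an unadjusted p below 0.05 the blocked fit had 2174 lower and 1606 higher, which turned to 1710 lower and 3188 higher without AEBP1 siRNA replicate 2. Among them, 201484_at fell by 1.86 (SE 0.18, limma adjusted p = 0.0358) and 202441_at fell by 1.71 (SE 0.21, limma adjusted p = 0.0497). Probe sets 236126_at and 226793_at did not pass, with limma adjusted p of 0.0530 and 0.0698 with the block. The same blocked fit called 0 without the filter on dim probe sets, where the adjusted p of 201484_at was 0.394, 225 with quantile normalization and 395 with an intensity trend and robust variances.

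Within the sets, from the lowest to the highest spike-in level, AEBP1 siRNA minus scrambled siRNA was -2.26, -1.88, -1.86 and -1.45 at 201484_at and -2.52, -1.29, -1.60 and -1.49 at 202441_at. The numbers of probe sets at least 1 log2 unit higher were 312, 417, 569 and 1037, and at least 1 unit lower 3153, 222, 416 and 1011. The 3153 come from the set whose AEBP1 siRNA array is replicate 2, which stood apart from its group with a 75th percentile of 6.55 against 6.99 to 7.02. At least 1 unit of difference in the same direction in all 4 sets was seen at 22 probe sets, 16 lower and 6 higher; exchanging the sign of 1 or more sets gave at most 2. No probe set was called with the block when any of the 9 arrays was left out, with lowest adjusted p of 0.0677 to 0.202. The differences stayed about as large, from -1.99 to -1.74 at 201484_at and from -1.84 to -1.47 at 202441_at. These are 6 distinct fits with 3 residual degrees of freedom, since without 1 array of a pair the other carries no comparison.

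**Figure D1:**
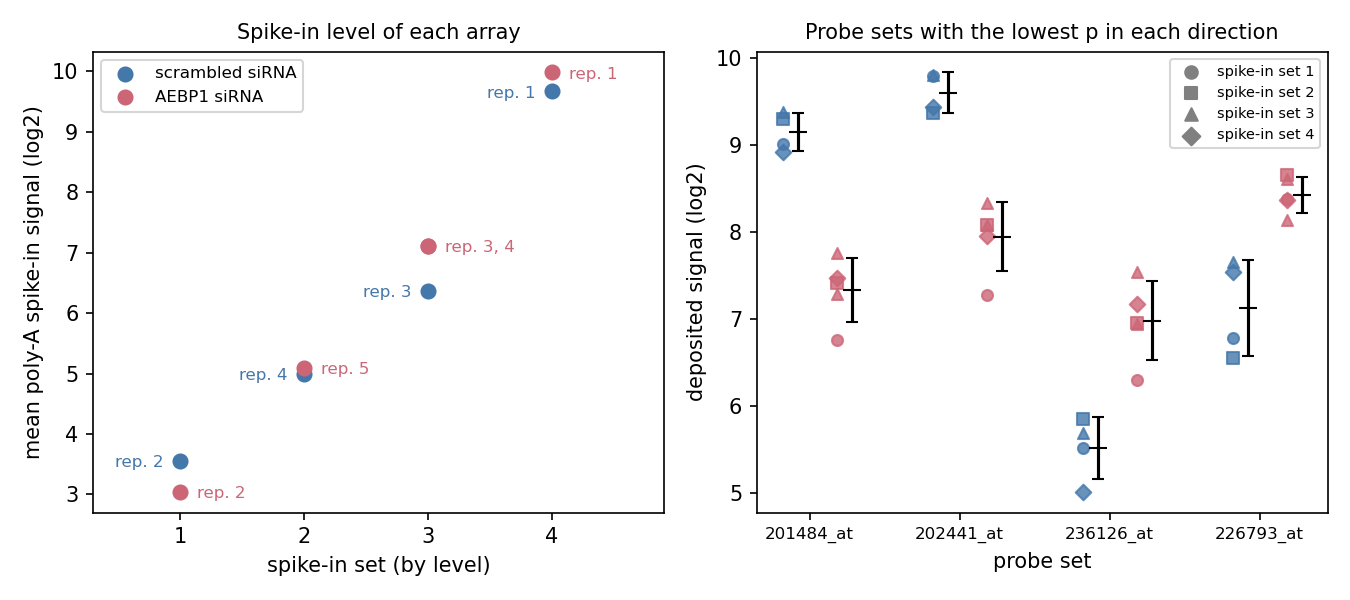
Left, mean log2 signal of the poly-A spike-in controls on each of the 9 arrays against its spike-in set, with replicate numbers beside the points. Right, deposited log2 signal of the 4 printed probe sets on each array, by group (colour) and spike-in set (marker), with bars for mean ± SD (n = 4 and n = 5); both groups occur in each of the 4 sets, and the groups do not overlap at these probe sets.

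Other control probe sets also differed between arrays. The 5' minus 3' log2 signal of the actin control, which drops when RNA or cDNA is shortened, was -2.67 and -2.82 on AEBP1 siRNA replicates 3 and 4 and between -1.57 and -1.17 on the other 7 arrays. Group means were -1.41 ± 0.20 (SD, n = 4) for scrambled and -1.88 ± 0.80 (SD, n = 5) for AEBP1 siRNA (two-sided exact permutation test, p = 0.397; Benjamini-Hochberg p = 1 over 6 array measures). The same measure for the GAPDH control was -0.17 ± 0.12 (SD, n = 4) and -0.22 ± 0.15 (SD, n = 5; exact permutation p = 0.492). Without the 2 arrays with the low actin value, limma again called 0 probe sets and 881 had an unadjusted p below 0.05. Of these, 691 were lower and 190 higher with AEBP1 siRNA, against 673 and 462 with all 9 arrays. The fit with spike-in sets as a block was not run without these 2 arrays.

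The second comparison asks where AEBP1 sits on promoters. The procedure called 368 regions, 121 on design 1 and 247 on design 2, near 352 genes. The ratios given here are means over the probes of the highest window in each region. For the 10 named regions they are lower over the whole interval wherever the region is wider than that window. The highest was on chromosome X from 123303103 to 123304310 (hg18) at SH2D1A, an adaptor of lymphocyte receptor signalling, with log2 ratios of 2.26 and 3.47 in immunoprecipitations 1 and 2 over the 4 probes of that window, and 1.61 and 1.98 over all 6 probes of the interval. Next came chromosome 11 from 117452605 to 117453541 at TMPRSS4, a transmembrane serine protease, with 2.12 and 3.69 (1.79 and 1.99 over all 6 probes), and chromosome 20 from 18072791 to 18073222 at CSRP2BP, with 2.09 and 3.92. The remaining regions of the 10 were at the olfactory receptor OR8A1 (chromosome 11 from 123943953 to 123944477, mean log2 ratio 2.87 ± 1.14, SD, n = 2), at the macrophage complement receptor VSIG4 (chromosome X from 65174695 to 65175678, 2.81 ± 1.06), at MAGEE1 (chromosome X from 75560193 to 75560648, 2.64 ± 0.95), and at NLRP13 (chromosome 19 from 61136164 to 61136851, 2.64 ± 0.67). The last of them were at the alcohol dehydrogenase gene ADH1A (chromosome 4 from 100432253 to 100433095, 2.86 ± 0.88), at C19orf18 and ZNF606 (chromosome 19 from 63179557 to 63180298, 2.58 ± 0.70) and at BEX5 (chromosome X from 101298191 to 101299707, 2.66 ± 1.05).

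These ratios rest on weak input signals. At SH2D1A, 0 of 6 probes were well above background in the Cy3 input channel on both arrays, and 3 of 6 in Cy5; at TMPRSS4 these were 2 and 6 of 6 probes, and at CSRP2BP 0 and 1 of 3. Over all 368 regions, 19.5% of probes were well above background in Cy3 and 63.1% in Cy5, against 81.1% and 82.3% of all probes. In 157 regions no probe was well above background in Cy3. Where the input is not well above background, the printed ratio is a value of the scanner software's processed signals and not a measured enrichment. The median GC content of the regions was 34.5%, against 42.6% for all windows, and 197 regions consisted of 1 called probe.

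**Figure D2:**
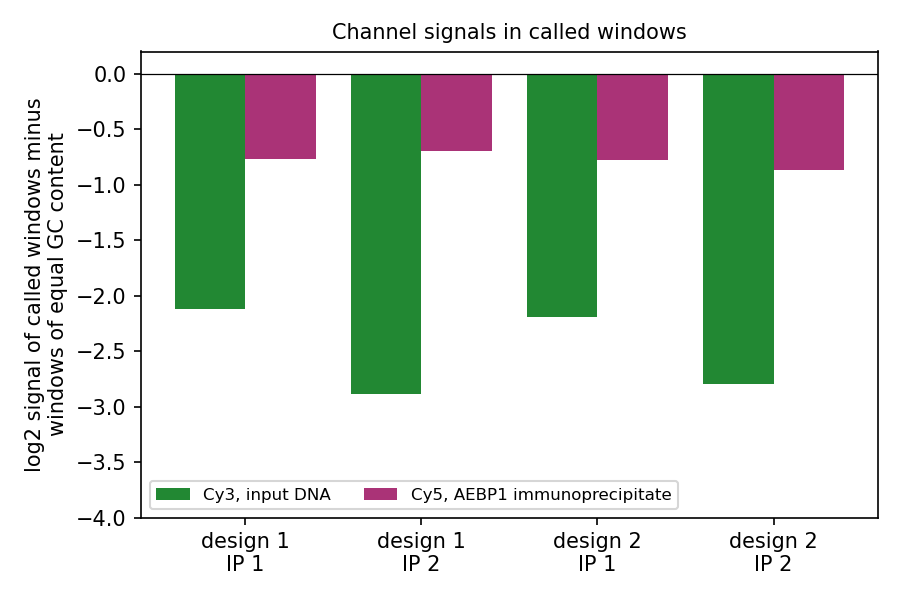
Mean log2 signal of called windows minus the median of windows of equal GC content, for the Cy3 input and the Cy5 immunoprecipitate channel on the 4 ChIP arrays. Cy3 lies between -2.89 and -2.12 and Cy5 between -0.86 and -0.70.

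**Figure D3:**
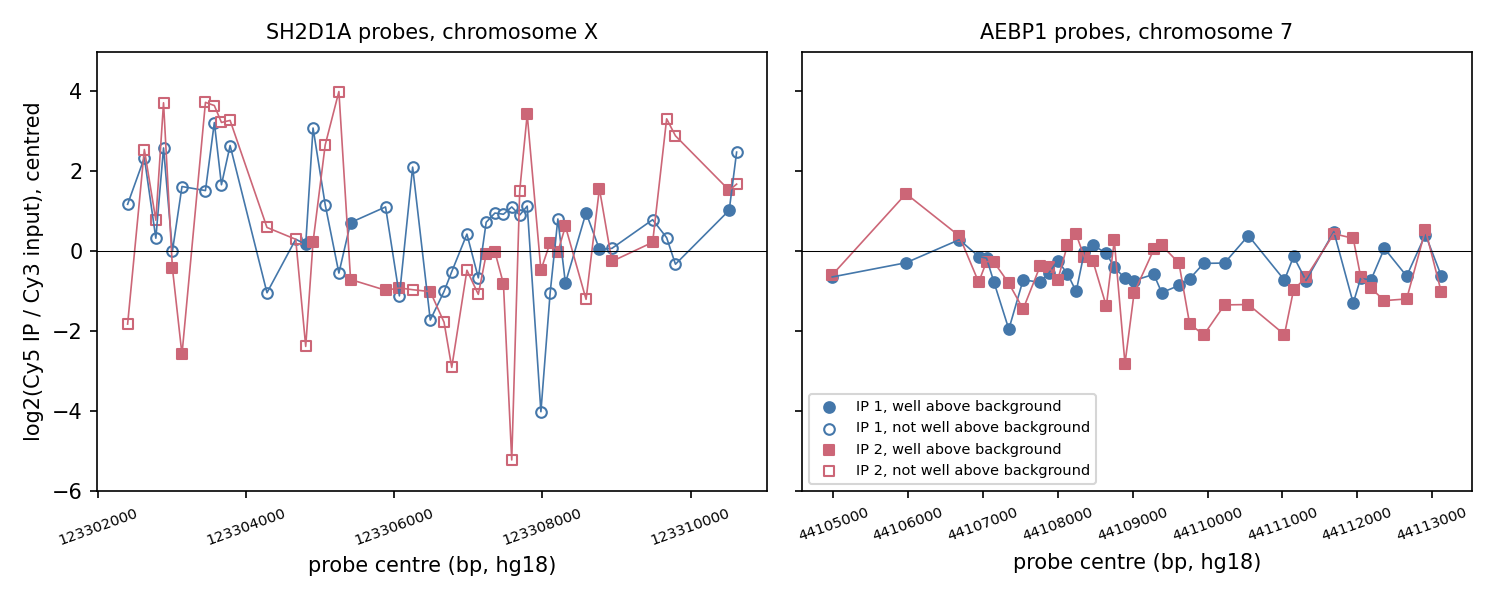
Centred log2 ratio of Cy5 immunoprecipitate over Cy3 input for each probe named for SH2D1A (left, chromosome X) and AEBP1 (right, chromosome 7) against the probe's centre in bp of hg18. Filled points are well above background in both channels and open points are not; the SH2D1A region from 123303103 to 123304310 holds open points except 1 probe in immunoprecipitation 2, which lies at -2.58, and the AEBP1 probes are filled and lie mostly below 0.

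The promoter of AEBP1 itself carried no region. Its 37 probes on chromosome 7 from 44104962 to 44113145, all well above background, had mean log2 ratios of -0.46 ± 0.50 and -0.61 ± 0.87 (SD over probes) in the immunoprecipitations, and its highest window reached z-scores of -0.36 and -0.36, below the threshold of 2.5. FABP4, the adipocyte gene whose enhancer gave AEBP1 its name, was looked at outside the rule: its 37 probes on chromosome 8 from 82555489 to 82563488, of which 13 were well above background, had mean log2 ratios of 0.02 ± 1.06 and 0.92 ± 1.61 (SD over probes), and its highest window had a lower z-score of 1.41, below the threshold of 2.5.

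The regions depended strongly on the settings. With only probes well above background in both channels on both arrays, 5 regions were called, at a threshold of 3.2 on both designs. Only 21 of the 368 regions held at least 3 such probes, the number a window needs, so the others could not be called there. With normexp background correction 0 regions were called. It was run with an offset of 50 on the mean signals, without the scanner software's detrending or dye normalization. An offset draws the ratios of dim probes towards 0, so this count cannot tell false regions from dim ones. With the median of GC content classes subtracted, a setting chosen after the data were seen, 80 regions were called at thresholds of 3.8 and 3.1, and 78 of the 368 regions kept a called window, among them all 10 named here. At the thresholds of 2.5 and 2.6 used without this correction, the windows high in both immunoprecipitations went from 211 to 351 on design 1 and from 461 to 371 on design 2, while those equally low rose from 10 to 38 and from 23 to 38. Called on immunoprecipitation 2 alone (without replicate 1) there were 1814 regions, and on immunoprecipitation 1 alone (without replicate 2) 6. Of the 368 regions, 175 and 0 kept a called window there. Of the 10 named regions, 0 were called with normexp. On immunoprecipitation 1 alone 0 were called as well, at thresholds of 5.5 and 6.1 on designs 1 and 2.

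Of the 27 gene lists, 24 had no member with a region, among them the p53 targets (0 of 20 measured members), the mitosis genes (0 of 29), the interferon response genes (0 of 28), the PPAR and LXR lipid targets (0 of 22), the extracellular matrix genes (0 of 28), the NF-kB targets (0 of 24), the TGF-beta targets (0 of 20) and the glial and glioma genes (0 of 24). Over all genes, 352 of 17626 (2.00%) had a region. At this share a list of 9 to 29 measured genes most often holds 0 members with a region by chance. A count of 0 therefore cannot show that AEBP1 is absent from a list. The neuronal markers had 2 of 14, the microtubule-associated MAP2 and DCX (Fisher's exact test p = 0.0309, Benjamini-Hochberg p = 0.834 over the lists). The PI3K and AKT pathway had 1 of 19, the PI3K regulatory subunit PIK3R1, and the MAPK immediate early list 1 of 25, SPRY2, an inhibitor of ERK signalling. No list passed the threshold. The remaining lists with 0 members were the pro-apoptotic (of 26), anti-apoptotic (of 12), DNA replication and S phase (of 29), cell cycle inhibitor and G1 cyclin (of 14), cholesterol synthesis (of 22), matrix protease and inhibitor (of 22), ER stress (of 22), hypoxia and glycolysis (of 24), oxidative stress response (of 16), replication-dependent histone (of 12), ribosomal protein (of 24), proteasome (of 24), oligodendrocyte (of 10), immune cell (of 14), endothelial (of 10) and epithelial (of 9) lists.

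Agreement between the immunoprecipitations was weak. Across probes, Pearson's r was 0.106 on design 1 and 0.101 on design 2, with Spearman's rho of 0.141 and 0.129. Across 500 bp windows, r was 0.231 and 0.210, with rho of 0.266 and 0.231. With only probes well above background in both channels, window r was 0.250 and 0.194. After the median of GC content classes was subtracted, window r was 0.0498 and 0.0605. Over all probes the log2 ratio fell with GC content on every array. Spearman's rho was -0.235 and -0.328 on design 1 and -0.201 and -0.312 on design 2 for immunoprecipitations 1 and 2. The fall did not hold over the whole range. In immunoprecipitation 1 the 10% of probes with the highest GC content had higher means than the 10% next to them. These means were -0.17 against -0.29 on design 1 and 0.01 against -0.20 on design 2. The spread also differed: the SD of the log2 ratio was 0.89 in immunoprecipitation 1 and 1.42 in immunoprecipitation 2 on design 1.

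**Figure D4:**
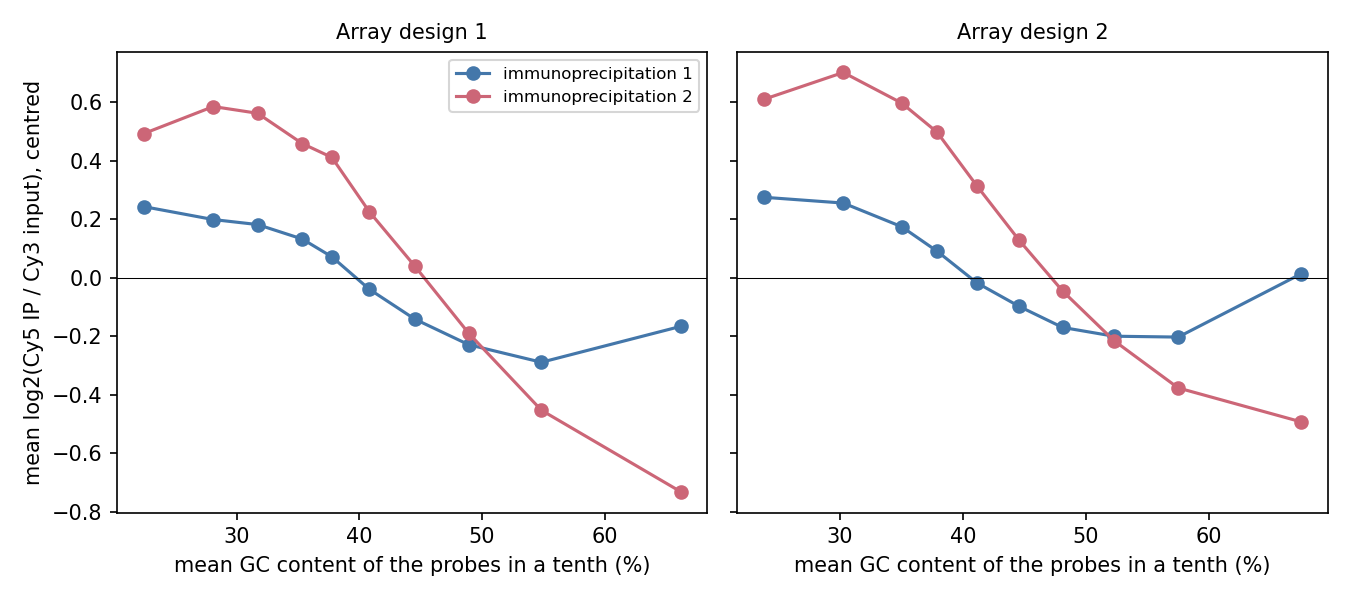
Mean centred log2 ratio of Cy5 immunoprecipitate over Cy3 input for 10 equal classes of the probes by GC content, for both immunoprecipitations on each array design. On design 1 the means run from 0.24 to -0.17 in immunoprecipitation 1 and from 0.49 to -0.73 in immunoprecipitation 2, from the class of lowest to that of highest GC content. In immunoprecipitation 1 the class next to the highest lies lower, at -0.29.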

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

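The sets by spike-in level and the tests on them, and the test on GC content, were chosen after the values were seen; the tests of other splits, of shifted arrays and of the input signal were set before their results were seen. A sample far from the others of its group was found for 2 of 28 groups of values, where chance alone flags about 5%. The 75th percentile of the log2 signal was 6.55 on AEBP1 siRNA replicate 2, with the other 4 between 6.99 and 7.02. On scrambled siRNA replicate 3 it was 6.99, with the other 3 at 6.91. Without AEBP1 siRNA replicate 2, limma called 0 probe sets, 2138 had an unadjusted p below 0.05, and the split turned to 1420 higher and 718 lower.

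For the probe sets called after AEBP1 silencing, other splits of the 9 arrays were tested. Without a block the real split called 0 probe sets, and so all 100 of 100 splits gave at least as many; the highest of the others called 1488. A count of 0 fixes this outcome; at an unadjusted p below 0.05, 39 of the 100 gave at least the real 1135, with 7609 the highest, so chance cannot be excluded without a block. The split with 1488 set scrambled replicates 1, 2 and 4 with AEBP1 siRNA replicates 2 and 5 against the arrays of the spike-in set of scrambled replicate 3 plus AEBP1 siRNA replicate 1, so it largely follows the spike-in sets and points to a structure of the samples other than silencing. A split of whole spike-in sets, with replicates 2 of both groups, scrambled replicate 3 and AEBP1 siRNA replicates 3 and 4 together, called 69. With the spike-in set as a block, labels were exchanged within sets. Of 24 such arrangements, 1, the real one, gave as many as 42 probe sets, and the highest of the others gave 0. This argues against chance only as far as 24 arrangements allow, with a block chosen after the data were seen. Leaving out any array gave 0 calls in designs with 3 residual degrees of freedom. Probe set 201484_at stayed between -1.99 and -1.74, which is no separate support, as it was chosen for a low p and groups without overlap. At an unadjusted p below 0.05 the real arrangement gave 3780 probe sets and the highest of the others 3131.

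The sets by spike-in level were weighed as a preparation batch and as an effect of silencing. After the group means were removed, residuals of probe sets correlated at 0.685 on average within sets, and none of the 1260 divisions of the arrays into sets of those sizes reached this except the spike-in division itself (highest other 0.430). This is consistent with arrays prepared or hybridised in 4 batches. Silencing as the origin of the sets is argued against by the range of the level within each group, from 3.56 to 9.67 in scrambled and from 3.05 to 9.98 in AEBP1 siRNA. The group means differed by 0.32 (two-sided exact permutation p = 0.833), which restates that each set holds both groups and adds no separate test. No label names a batch, so what the sets share stays open.

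Windows high in both immunoprecipitations numbered 672. Chance overlap of unrelated arrays is argued against as the whole cause, since shifting 1 array along the genome gave at most 250 in 100 draws (mean 179), and so is the shared GC trend as the whole cause, since exchanging windows within GC classes gave at most 321 (mean 281). These means are a large part of the 672, while the mirrored lower tail held 10 and 23 windows on designs 1 and 2. The share of false windows may therefore lie well above 5%. A low input signal remains as a candidate explanation: in called windows the Cy3 input signal lay below windows of equal GC content by a deficit that made up 123% of the log2 ratio. The mean differences were -2.50 for Cy3 and -0.78 for Cy5, so the Cy5 signal was not above that of windows of equal GC content either. These windows were called for a high ratio of Cy5 over Cy3, which by itself favours windows of low Cy3. The deficit therefore cannot decide between a weak input and an enrichment over it. Binding by AEBP1 cannot be separated from a low input signal here, as no array is labelled as an immunoglobulin control and the dyes were not swapped. The series text names rabbit IgG while the sample labels name input DNA in Cy3, so what the control channel held rests on the sample labels alone.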

How the results depend on the processing

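The blocked fits on spike-in sets, the fit without the arrays of low actin value and the GC correction were chosen after the data were seen. For expression, 0 probe sets were called in every alternative fixed before the data were examined that could be run, except quantile normalization, which called 1. Leaving out each array in turn gave 0 to 0 calls, with 713 to 2138 probe sets at an unadjusted p below 0.05 (limma). The replicate block called 0, with 2899 at an unadjusted p below 0.05 (limma). Residual correlations between arrays of the same number were 0.587, 0.640 and 0.786 for numbers 1 to 3, the best match of each of these scrambled arrays. For number 4 the correlation was -0.374, and its scrambled array correlated best with AEBP1 siRNA replicate 5. Replicate numbers thus paired the samples at numbers 1 to 3 and not at number 4. With spike-in sets as a block, 42 probe sets were called, 395 with an intensity trend and robust variances as well, 225 with quantile normalization as well, and 0 without the filter or with any array left out; the cause was not tested.

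The 368 ChIP regions became 0 with normexp, 5 with probes well above background, 243 with 250 bp and 660 with 1000 bp windows, 81 at an error rate of 1%, 594 by the mean of the z-scores, 80 with GC classes subtracted, and 6 to 1814 without replicate 2 or 1. Of the 368, only 21 held at least 3 probes well above background in both channels, the number a window needs. Design 1 fell from 121 regions to 8 and 19 with 250 and 1000 bp windows, where its threshold rose from 2.5 to 3.5 and 3.2. With 250 bp, 140729 of its windows held enough probes, against 214015 with 500 bp. Of the 10 named regions, 6 had a value with 250 bp, and these were called. Design 1 had 3 regions at 1%, 6 by the mean and 6 with GC classes subtracted, at thresholds of 3.8, 3.9 and 3.8. Only 78, 146 and 249 of the 368 regions kept a called window with 250 bp, 1000 bp and the mean. The mean window correlation of 0.220 became 0.145 with normexp, 0.193 and 0.260 with 250 and 1000 bp, and 0.0552 with GC classes subtracted, and stayed at 0.222 with probes well above background. With normexp, whose offset of 50 draws the ratios of dim probes towards 0, 0 of the 10 named regions were called. The region at C19orf18 turned from a lower z-score of 4.20 to -0.0200, and SH2D1A went from 4.75 to 0.252. TMPRSS4 kept 3.38 and ADH1A 1.87, and the others lay at or below the 0.601 of BEX5. The cause was not tested. Scaling arrays to a common spread cannot move the z-scores. No gene list passed in any setting. With normexp, with probes well above background and without replicate 2, only 0, 5 and 6 genes had a region. None of them was in a list, so no list could have passed there. The named probe sets kept their direction in all 116 values. They were chosen for groups without overlap, so leaving out arrays, changing the filter or adding the spike-in block could not turn it. This is therefore no separate support for them. Alternatives on the probe set standing for a gene, the AEBP1 transcript, gene lists in expression and bound among changed genes were not run, as no table used here names the expression probe sets.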

Other observations

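All tests on gene families were chosen only after the region list was seen, as was the naming of the bright-probe regions, whose setting was fixed before the data were examined; what the brightness test would show if weak signal were the cause was written before it was run, and so was the GAAAT test. Olfactory receptor genes were common among the genes with a region: 36 of 294 (12.2%), against 2.00% of all genes (Fisher's exact test, odds ratio 7.51, p = 2.28e-18 across genes, which are not independent replicates). Among them were OR8A1, OR4K14 and OR5B3, with lower z-scores of 4.47, 3.70 and 3.68. Zinc finger genes named ZNF had a region in 18 of 394 (4.57%; odds ratio 2.42, Fisher's exact test p = 0.00134 across genes). For these ZNF genes the odds ratio was 1.63 (95% interval 0.989 to 2.68) within 5 equal classes of the share of probes well above background and its 95% interval was 0.910 to 2.48 within 20 finer classes, so both intervals include 1 and an excess among genes of like brightness was not established. An AT-rich sequence does not account for all of the olfactory receptor share, since the odds ratio within 10 classes of GC content was 3.83 (95% interval 2.61 to 5.64). Weak signal could account for a large part: the odds ratio was 1.89 within 5 equal classes of the share of probes well above background. Its 95% interval of 1.30 to 2.75 left out 1, so by the criterion written beforehand weak signal does not account for all of it. All 36 lay in the dimmest of these classes, so differences in brightness remained within it. In 20 finer classes, chosen after this value was seen, the odds ratio was 1.31 (95% interval 0.890 to 1.94). Only 26.9% of the probes of olfactory receptor genes were well above background, against 77.8% for all genes.

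With only bright probes, the 5 regions were at CTSO, OR5B21, TNFSF11, CCDC102B and C20orf186 (now BPIFB4), named here because they are few. Those at CTSO (chromosome 4 from 157091995 to 157092044, hg18), C20orf186 (chromosome 20 from 31134883 to 31134942) and OR5B21 (chromosome 11 from 58035640 to 58036450) overlapped regions called with all probes. At C20orf186, the log2 ratios of the bright probes were 1.94 and 2.22 and the window's GC content was 50.7%, above the median of all windows. At CTSO, a cysteine protease, the log2 ratios were 1.35 and 2.57. With GC classes subtracted, a setting run on all probes and not only on bright ones, the lower z-score was 3.70 at C20orf186, above the threshold of 3.1 on its design. It was 1.06 at OR5B21, 2.01 at TNFSF11 and 1.42 at CCDC102B, below that threshold, and 2.80 at CTSO, below the threshold of 3.8 on design 1. As the dim probes came back as well, these low values cannot be put down to GC content alone.

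Whole promoters of the fixed lists were also compared with 10000 random lists matched on GC content and number of probes, using GC-corrected ratios averaged over each gene. No list lay outside the central 95% of random lists, on the same side, in both immunoprecipitations. In immunoprecipitation 2, 10 lists lay at or below the 2.5th percentile, and in immunoprecipitation 1, 0. The lowest were the MAPK immediate early genes, with a median log2 ratio of -0.29 in immunoprecipitation 2 and -0.14 (percentile 5.19) in immunoprecipitation 1, and the hypoxia and glycolysis genes, with -0.22 and -0.10 (percentile 20.8).

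The pentamer GAAAT, recalled as a sequence reported for AEBP1 targets, was tested as a hypothesis of sequence preference. Among the 20 pentamers of its base composition, it ranked between 6 and 18 in the difference of GC-corrected log2 ratio between probes with and without it, and that difference lay between -0.02 and 0.02 on the 4 arrays. These ratios therefore gave no sign that GAAAT raises them beyond base composition.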
